A study of Mus musculus with 14 samples.

How the data were processed

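Hypothalamic RNA of 14 samples from mice 12 weeks old was measured on Affymetrix HT MG-430 PM arrays, from 150 ng of RNA each. The mice had a mixed background of 3 strains. Control mice and mice with Mfn1 deleted in POMC neurons were either fed or fasted for 16 h. The 4 groups were control fed (n = 4), control fasted (n = 3), knockout fed (n = 4) and knockout fasted (n = 3). The labels do not say whether each array holds 1 mouse, so p-values measure the spread between these samples. The numbers in the sample titles are all different and pair no samples.

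The deposited values are log2 expression values made with RMA and affy, per the submitters' processing notes, which give no versions. RMA corrects the background, normalises the arrays to a common distribution and summarises the probes of each probe set, so small differences of low probe sets are compressed. The genome build behind the probe set annotation is not given in the sources used here. All values were used as deposited, with no further normalisation. Array medians lay between 4.98 and 5.05, and Pearson's r between arrays, across probe sets, between 0.9908 and 0.9968. No pair of arrays shared more than 2.9% identical values at 2 decimals, so each array was counted as 1 sample. The 23 probe sets without a target that match the GC content of probes had a median of 3.64, which marks the level of background signal. The number of arrays limits the precision of every difference. No column of the deposited table was left out of the comparisons.

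The table holds 45141 probe sets. Gene names came from the platform annotation, in which 28898 probe sets named 1 gene and 551 named several, and 15692 had no name in it. Of the gene IDs, 99.3% matched the RefSeq table of GRCm38.p6, and 0 symbols changed. That table was used only for names, for chromosomes and for which genes neighbour each other. Probe sets naming several genes, or none, were not tested. Each of the 17097 genes tested was represented by the probe set with the highest mean over all arrays, and 7180 genes had more than 1 probe set.

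Differences were fitted with limma 3.58.1 in R 4.3.3, with lmFit on 1 coefficient per group over all 14 arrays, contrasts and eBayes. The residual degrees of freedom were 10 and the prior degrees of freedom 3.27. All tests were two-sided, p-values were adjusted over all genes tested by the Benjamini-Hochberg method, and the threshold was an adjusted p of 0.05. The 7 contrasts were fasted against fed in each genotype, knockout against control in each feeding state, both differences averaged with equal weight, and the interaction, which is the fasting difference of knockout mice minus that of control mice. Errors of log2 differences are standard errors (SE) of this fit.

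Before the data were examined, 39 gene lists with 645 members were fixed, of feeding peptides, hormone-responsive genes, metabolic and stress pathways and markers of cell types and of neighbouring brain regions. Of the members, 563 were measured. The sex-linked list served only to check the arrays, which all had the same pattern. The other 38 lists were tested with limma's camera at a preset correlation between genes of 0.01, and again with the correlation estimated per list, with adjustment over the lists of a contrast. Member counts were adjusted over the list alone and over all genes. A list score of an array is the mean of its members' log2 values, each centred on its mean over all arrays. Of 6 single genes fixed for every contrast, 5 were measured and 1 is not reported here.

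The named genes followed a rule fixed at the same time. It took the single fixed genes, then up to 10 genes per direction with the largest absolute log2 difference among those past the threshold, or the 5 with the smallest unadjusted p where fewer than 5 passed. It also took up to 6 members with the smallest p of each list past its threshold and up to 3 of other lists. Symbols that are only clone or model numbers were counted but not named. Genes named outside this rule are marked as chosen after their values were seen.

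The pipeline was tested on simulated data with 200 of the 17097 genes changed and noise drawn independently for each gene. With a log2 change of 0.5, it recovered 69% of the changed genes in both fasting contrasts, 73% in the genotype contrast of fed mice and 70% in that of fasted mice. For the averaged contrasts the share was 94% for fasting and 93% for genotype, and for the interaction it was 39%. With a log2 change of 1, the shares were 97% for fasting in either genotype, 99% and 95% for genotype in fed and fasted mice, 98% and 99% for the averaged fasting and genotype contrasts, and 92% for the interaction. False calls lay between 2 and 12 per contrast. Where fewer genes change the adjustment is stricter, so these shares do not give the power of contrasts in which hardly any gene passes.

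Alternatives fixed at the outset were a filter on the 40% of genes with the lowest mean, the mean of a gene's probe sets, every probe set tested, quantile normalisation, subtracted array medians, a trended and robust prior, array weights, the 3' to 5' control difference as a covariate, only the groups compared, the estimated correlation, Spearman's correlation and each array left out in turn. The choroid plexus score as a covariate and the series of the title numbers as a covariate were added after seeing the data. Other splits of the same arrays were counted for each contrast, all of them or 100 drawn at random. Python 3.11.15 and matplotlib 3.10.9 drew the plots.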

Results

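RNA of the hypothalamus, the brain region that senses energy state and controls feeding, was measured on 14 arrays in 4 groups. These were control fed (n = 4), control fasted (n = 3), knockout fed (n = 4) and knockout fasted (n = 3), where the knockout removes Mfn1 from the neurons that express pro-opiomelanocortin (POMC). The series title links this mitochondrial fusion protein in POMC neurons to glucose sensing and insulin release. The comparisons ask how a 16 h fast and the deletion change hypothalamic expression, and whether the fasting response differs between the genotypes. The 3' minus 5' difference of the control probe sets, a sign of RNA quality, lay between -0.03 and 0.12 for Gapdh and between 0.77 and 0.94 for Actb.

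Mfn1 was at 9.04 ± 0.06 (SD, n = 4) in control fed mice and at 9.06 ± 0.01 (SD, n = 3) in control fasted mice on the log2 scale. In knockout mice it was at 9.06 ± 0.04 in the fed (n = 4) and in the fasted group (n = 3). The averaged genotype difference was 0.01 ± 0.03 (SE), with an adjusted p of 0.999. POMC neurons are a small part of this tissue, and its 3 probe sets may lie outside the deleted part, so this value does not check the labels. Mfn2, the second mitofusin, differed by -0.04 ± 0.04 (adjusted p = 0.999). Pomc, the precursor of the satiety peptide alpha-MSH, differed by 0.25 ± 0.26, and Cartpt, a peptide made in the same neurons, by 0.05 ± 0.13 (adjusted p = 0.999 each). Control fed replicate 1 had the lowest values of both genes, 5.68 for Pomc and 8.84 for Cartpt, against 6.48 and 9.50 or more on every other array.

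**Figure D1:**
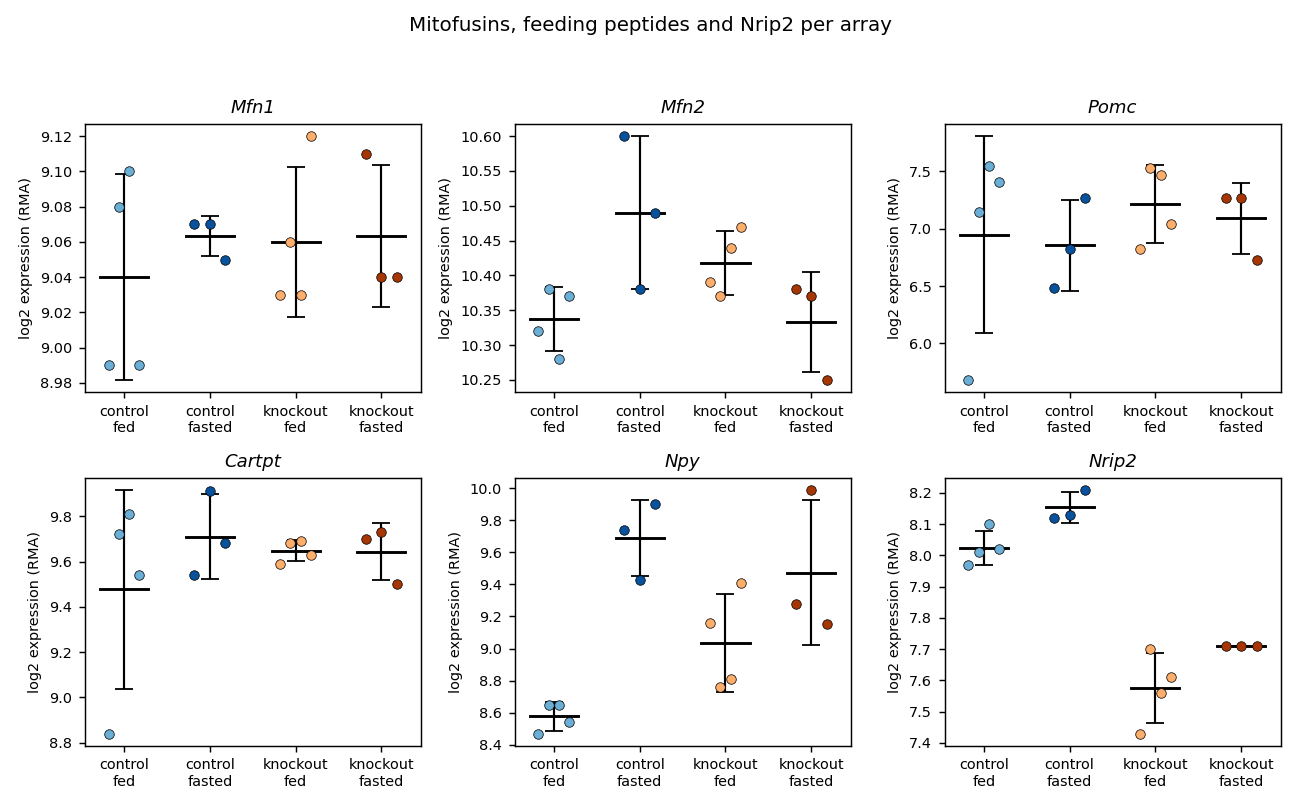
Log2 expression (RMA) of Mfn1, Mfn2, Pomc, Cartpt, Npy and Nrip2 in each array, by group. Horizontal lines are group means and bars are ± SD (n = 4 fed and n = 3 fasted arrays per genotype); Nrip2 lay at 7.97 to 8.21 in controls and at 7.43 to 7.71 in knockouts.

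Fed and fasted mice differed in many genes. Averaged over genotypes (n = 6 fasted, 8 fed), the lipid droplet protein gene Plin4 rose by 3.41 ± 0.25 (SE, log2) and the cell cycle inhibitor Cdkn1a by 3.07 ± 0.35. Sult1a1, a sulfotransferase, rose by 2.54 ± 0.15, and Mfsd2a, a transporter of lysophospholipids at the blood-brain barrier, by 1.85 ± 0.12. Arrdc2, the kinase genes Sgk1 and Sgk3, the transcription factor Zbtb16, Phyhd1 and the matricellular gene Ccn2 rose by 1.49 to 1.77. Npy, the main orexigenic peptide of the arcuate nucleus, rose by 0.78 ± 0.14 (adjusted p = 0.00432). Pomc was at -0.11 ± 0.26 and Cartpt at 0.11 ± 0.13, with adjusted p of 0.839 and 0.619.

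Among genes lower after the fast, Fabp7, a fatty acid binding protein of glia, fell by 1.24 ± 0.13, the oligodendrocyte gene Opalin by 1.19 ± 0.16 and Ugt8a, which makes the myelin lipid galactosylceramide, by 1.02 ± 0.11. With the mean of its probe sets Opalin was at -0.58 and still passed. Of genes that interferons induce, Tgtp1 fell by 1.62 ± 0.35 and Ifit3 by 1.32 ± 0.22, and Iigp1, Ifi27l2a, Ifit1, Gbp10 and Oasl2 fell as well, with log2 differences of -1.23 to -0.99. Knockout fed replicate 1 was at the level of fasted mice for these genes, for example 6.76 for Ifit3 against 8.25 or more on the other fed arrays. With the number series of the samples as a covariate, the sign turned for Ifit3 (0.054), Iigp1 (0.06), Ifit1 (0.16) and Oasl2 (0.04), and Tgtp1 was at -0.01, Ifi27l2a at -0.04 and Gbp10 at -0.16.

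In all, 1715 of 17097 genes passed in limma, 878 higher and 837 lower, and 4448 had an unadjusted p under 0.05 where chance gives 855. Of the 1715, 38 changed by more than 1 on the log2 scale, and over all genes 3.4% had no overlap between fed and fasted arrays, where chance gives 0.0666%. Without knockout fasted replicate 2 the count was 998. All 6 fasted arrays and knockout fed replicate 1 have sample numbers from a low series and the other 7 fed arrays from a high series, so fasting is almost inseparable from any difference between these series. With the series as a covariate, which rests on that 1 fed array, 15 genes passed, 12 of them among the 1715, and 1682 of the 1715 kept their sign.

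**Figure D2:**
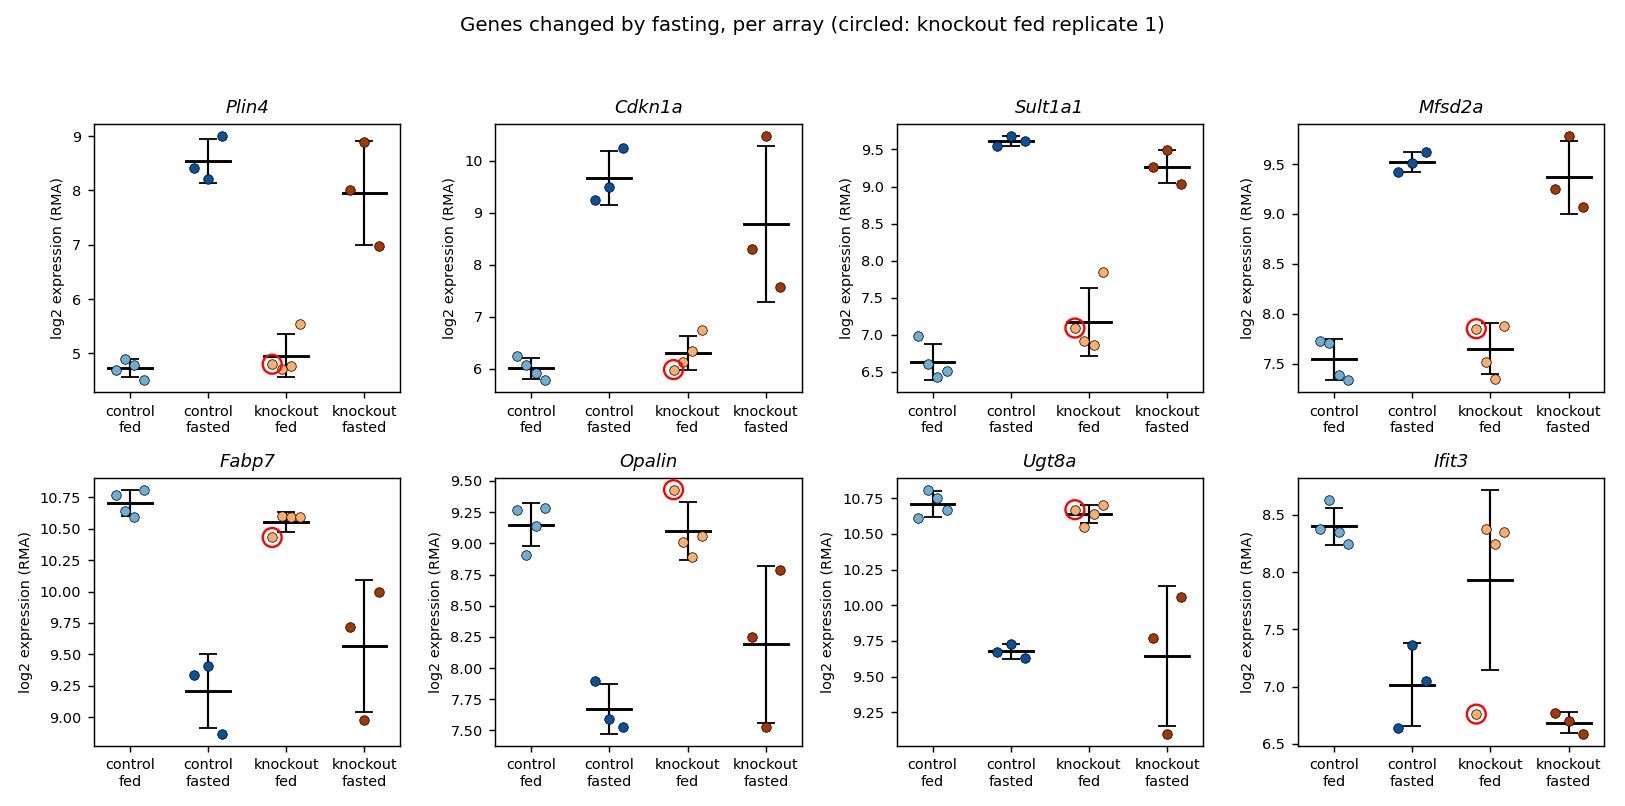
Log2 expression (RMA) of 8 genes that differed between fed and fasted arrays, shown for each array by group, with group means and ± SD (n = 4 fed and n = 3 fasted arrays per genotype). The circled array, knockout fed replicate 1, lay with the fed arrays for Plin4, Cdkn1a and Opalin and at 6.76, with the fasted arrays, for Ifit3.

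Glucocorticoid-responsive genes were the group with the strongest rise after the fast. Of 24 measured members 21 rose and 1 fell, both over all genes and adjusted over the list alone, with a median of 1.02. Among them were Sult1a1, Mfsd2a, Plin4, the metallothionein Mt1 (0.70 ± 0.05), Fam107a (0.55 ± 0.05) and the protease Htra1 (0.93 ± 0.08). The 1 lower member, chosen after its values were seen, was Nr3c1, the glucocorticoid receptor, at -0.21 ± 0.05. The list was higher with an adjusted p of 4.22e-25 in camera, and adjusted p = 0.191 with an estimated correlation. FOXO and fasting-responsive genes were higher too (adjusted p = 0.000462), with adjusted p = 0.191 with an estimated correlation. Of 17 members 8 rose over all genes, and 11 rose and 1 fell adjusted over the list alone. Txnip, which limits glucose uptake, rose by 1.47 ± 0.22, the mTOR inhibitor Ddit4 by 1.17 ± 0.15, Klf15 by 0.70 ± 0.15 and Sesn1 by 0.45 ± 0.08.

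Cholesterol synthesis genes were lower (adjusted p = 0.000159; adjusted p = 0.31 with an estimated correlation). Of 19 members 9 fell over all genes and 12 adjusted over the list alone, and none rose in either count. Fdps fell by 0.27 ± 0.05, Sqle, which makes squalene epoxide, by 0.25 ± 0.05, and the regulator Srebf2 by 0.22 ± 0.04. Markers of orexigenic arcuate neurons were higher as a list (adjusted p = 0.0119; adjusted p = 0.31 with an estimated correlation). In both counts 4 of 9 rose, namely Npy, Acvr1c (0.41 ± 0.06, and 0.26 with the mean of its probe sets), the ghrelin receptor Ghsr (0.39 ± 0.08) and Serpina3n (0.36 ± 0.08), while the receptor Npy2r fell by 0.43 ± 0.10. Leaving out the 40% of genes with the lowest mean ended this list call in the average (adjusted p = 0.0997), in control mice (0.0564) and in knockout mice (0.223).

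Heat shock genes were lower (adjusted p = 0.00198; adjusted p = 0.606 with an estimated correlation). The chaperone genes Chordc1 (-0.49 ± 0.09), Cryab (-0.36 ± 0.06), Hsph1 (-0.27 ± 0.05) and Hspb1 (-0.56 ± 0.15) fell and the co-chaperone Bag3 rose by 0.27 ± 0.08, which makes 4 lower and 1 higher of 13, or 6 and 1 adjusted over the list alone. Bag3 passed in 6 and Hspb1 in 10 of the 21 alternatives fixed at the outset, with Hspb1 at -0.27 with the mean of its probe sets, and the sign of Hspb1 turned with the number series as a covariate (0.034). The integrated and mitochondrial stress response was higher (adjusted p = 0.0444; adjusted p = 0.31 with an estimated correlation). Of its 22 members 4 rose over all genes, the serine synthesis enzyme Psat1 (0.47 ± 0.06), Slc3a2, Cth and Clpp, and 2 fell, the cystine transporter Slc7a11 (-0.79 ± 0.15, and -0.49 with the mean of its probe sets) and Vldlr. Adjusted over the list alone, 6 rose and 2 fell. This call was lost in 8 of the 14 fits that left out 1 array, with an adjusted p up to 0.0881, with the 40% filter (0.0614) and with the choroid plexus score as a covariate (0.0527), and Clpp passed in 13 of 21 alternatives. Oxidative phosphorylation genes were higher as a list (adjusted p = 0.0119; adjusted p = 0.606 with an estimated correlation) with a median of only 0.03. Of 70 members, Sdhc (0.16 ± 0.04) and Sdhd (0.19 ± 0.05) rose over all genes and 0 adjusted over the list alone, and Sdhd passed in 12 of 21 alternatives. Without knockout fasted replicate 1 this adjusted p was 0.0507.

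Markers of other cell types also differed between fed and fasted arrays. Microglial markers were lower (adjusted p = 0.000545; adjusted p = 0.191 with an estimated correlation). Of 10 members 5 fell in both counts, with P2ry12 at -0.77 ± 0.10, Aif1 at -0.72 ± 0.11, Cx3cr1 at -0.58 ± 0.16, Trem2 at -0.52 ± 0.07 and Tyrobp at -0.35 ± 0.06. Cx3cr1 passed in 11 of 21 alternatives and was at -0.38 without knockout fasted replicate 2, and Trem2 was at -0.28 with the mean of its probe sets. Knockout fed replicate 1, of the low number series, had a microglial score of -0.014. That is below the other fed arrays (0.074 to 0.245) and within the fasted arrays (-0.312 to -0.011). The fall of this list is therefore not separated from a difference between the number series. Astrocyte markers were higher (adjusted p = 0.0119; adjusted p = 0.31 with an estimated correlation), with 4 of 12 higher and 1 lower in both counts. Gjb6 rose by 0.72 ± 0.08, Fgfr3 by 0.60 ± 0.05, Agt by 0.56 ± 0.05 and Aldh1l1 by 0.33 ± 0.04, and the water channel gene Aqp4 fell by 0.36 ± 0.06. Markers of cortex and hippocampus were lower (adjusted p = 0.0119; adjusted p = 0.606 with an estimated correlation), with Prox1 (-0.31 ± 0.08) lower of 11 over all genes and 2 adjusted over the list alone. Prox1 passed in 10 of 21 alternatives and was at -0.07 with the mean of its probe sets (adjusted p = 0.467), and the 40% filter ended the list call (adjusted p = 0.148). The score of this list was 0.80 in control fed replicate 1 and 0.46 in knockout fed replicate 4, against -0.13 to 0.02 in the other fed arrays. The fixed lists overlap, since Gjb6 is also on the glucocorticoid list and Serpina3n on that of inflammation and gliosis. The other 28 lists did not pass, with adjusted p between 0.0685 and 0.981.

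**Figure D3:**
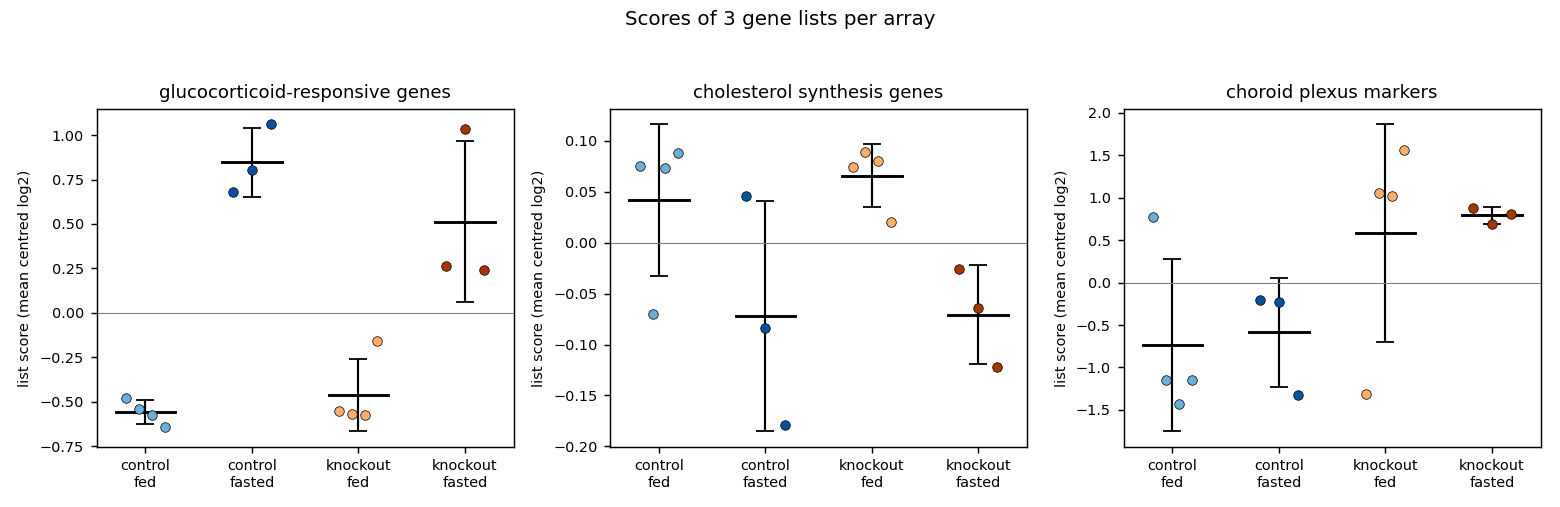
Scores of glucocorticoid-responsive genes, cholesterol synthesis genes and choroid plexus markers (mean centred log2) in each array, by group, with means and ± SD (n = 4 fed and n = 3 fasted arrays per genotype). The glucocorticoid score was -0.56 ± 0.07 in control fed and 0.85 ± 0.19 in control fasted mice, and the choroid plexus score ranged from -1.43 to 0.78 within the controls.

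In control mice alone, all fasted arrays are of the low number series and all fed arrays of the high one. No control array can therefore separate the fast from a series difference. Plin4 was higher after the fast by 3.82 ± 0.35, Cdkn1a by 3.65 ± 0.50, Sult1a1 by 2.98 ± 0.21 and Npy by 1.11 ± 0.20 (adjusted p = 0.00818, n = 3 fasted, 4 fed). Arrdc2, Sgk1, Ccn2, Mfsd2a, Sgk3, Zbtb16 and Phyhd1 rose by 1.83 to 2.31. Fabp7 fell by 1.496 ± 0.189, Opalin by 1.48 ± 0.23 (0.67 with the mean of its probe sets), Ly86, a gene of macrophages and microglia, by 1.05 ± 0.10, and Ifit3 by 1.39 ± 0.31. Gbp3, Gbp10, Oasl2 and Gbp2, which interferons induce, and Ugt8a and Olfml3 fell too, with log2 differences of -1.24 to -1.02. Of these calls, Ifit3 held in 15, Oasl2 in 16, Gbp3 in 18, Zbtb16 in 19, Gbp10 and Sgk3 in 21 and Olfml3 in 7 of 22 alternatives. With the number series as a covariate the sign turned for Ifit3 (0.18) and Oasl2 (0.03) in control mice, and 2 genes passed; this covariate is set by knockout fed replicate 1, which was low for these genes. In limma 472 genes passed, 280 higher and 192 lower, against 2986 at an unadjusted p under 0.05 (855 by chance). Over all genes, 16.51% had no overlap between fed and fasted control arrays, where chance gives 5.71%. The count was 216 without control fasted replicate 3, and 282 to 314 without control fasted replicate 1 or control fed replicate 2, 3 or 4.

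Of the lists, 8 passed in control mice. Glucocorticoid-responsive genes were higher, with 19 of 24 up over all genes and 21 up and 1 down adjusted over the list alone (adjusted p = 8.88e-30; adjusted p = 0.0941 with an estimated correlation). FOXO and fasting-responsive genes were higher (adjusted p = 0.000113; adjusted p = 0.0941 with an estimated correlation), with Ddit4, Txnip, Klf15, Sesn1 and Cited2 up over all genes and 8 adjusted over the list alone; Sesn1 held in 12, Cited2 in 10 and Klf15 in 16 of 22 alternatives. Microglial markers were lower, with Trem2, P2ry12, Tyrobp and Aif1 down over all genes and 7 of 10 adjusted over the list alone (adjusted p = 4.97e-05; adjusted p = 0.0941 with an estimated correlation). Astrocyte markers were higher (adjusted p = 0.00273; adjusted p = 0.164 with an estimated correlation), with Fgfr3, Agt, Gjb6 and Aldh1l1 up and Aqp4 down in both counts. Cholesterol synthesis was lower with Fdps, which held in 8 of 22 alternatives, down over all genes and 9 of 19 adjusted over the list alone (adjusted p = 0.00338; adjusted p = 0.5 with an estimated correlation). Heat shock genes were lower with Cryab and Hsph1, the latter in 12 of 22 alternatives, down over all genes, and 3 down and 1 up adjusted over the list alone (adjusted p = 0.00608; adjusted p = 0.5 with an estimated correlation). Oxidative phosphorylation was higher with no member past either count (adjusted p = 0.00656; adjusted p = 0.5 with an estimated correlation), and the mean of probe sets ended this call (0.0666). Markers of orexigenic arcuate neurons were higher with Npy and Acvr1c up over all genes, and 4 up and 1 down adjusted over the list alone (adjusted p = 0.0168; adjusted p = 0.471 with an estimated correlation). Leaving out 1 array lifted the adjusted p to 0.0724 for cholesterol synthesis (control fasted replicate 3), 0.0575 for oxidative phosphorylation (control fasted replicate 1), and 0.0516 and 0.051 for heat shock genes and arcuate markers (control fed replicate 2).

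In knockout mice only fed replicate 1 separates the fast from the number series. Plin4 was higher after the fast by 3.003 ± 0.348, Cdkn1a by 2.48 ± 0.50, Sult1a1 by 2.09 ± 0.21 and Mfsd2a by 1.72 ± 0.17 (n = 3 fasted, 4 fed). Ctla2a, Phyhd1, the glucocorticoid receptor co-chaperone Fkbp5, the lipase inhibitor Angptl4, Pnpla7 and Mertk rose by 0.92 to 1.34. Ugt8a fell by 1.00 ± 0.16, Fabp7 by 0.99 ± 0.19 and Ly86 by 0.76 ± 0.10, and Ninj2, Tst, Cav1, Gkn3, Pla2g4a, Dpy19l1 and Tubd1 fell with log2 differences of -0.78 to -0.64. Npy was at 0.44 ± 0.20 (adjusted p = 0.283). Many of these calls are weak. Cdkn1a (log2 1.64 to 3.09, adjusted p up to 0.185) and Fkbp5 held in 7 of 22 alternatives, Gkn3 in 7 of 21, Ctla2a and Cav1 in 8, Pla2g4a and Dpy19l1 in 9, Fabp7 and Mertk in 11 and Angptl4 in 16 of 22. Plin4, Sult1a1, Mfsd2a, Phyhd1, Ugt8a and Ly86 held in 21 or 22 of 22. In limma 119 genes passed, 80 higher and 39 lower, and 2816 had an unadjusted p under 0.05 (855 by chance). Over all genes, 13.01% had no overlap between fed and fasted knockout arrays, against 5.71% by chance. This count rested on single arrays: it was 18 without knockout fasted replicate 2, 59 without knockout fasted replicate 1, 363 without knockout fasted replicate 3, 40 and 37 without knockout fed replicates 2 and 3, and 63 to 71 without control fed replicate 2, 3 or 4 or control fasted replicate 2. It also moved with the method, to 10 with only the groups compared, 21 with the 3' to 5' covariate, 231 with the 40% filter, 341 with the trended and robust prior and 0 with the number series as a covariate.

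Of the lists, 9 passed in knockout mice. Glucocorticoid-responsive genes were higher, with 9 of 24 up over all genes and 20 adjusted over the list alone (adjusted p = 1.48e-20; adjusted p = 0.241 with an estimated correlation). Cholesterol synthesis was lower, with 0 of 19 down over all genes and 11 adjusted over the list alone (adjusted p = 1.63e-05; adjusted p = 0.403 with an estimated correlation). FOXO and fasting-responsive genes were higher with 0 and 4 members up in these counts (adjusted p = 0.00957; adjusted p = 0.403 with an estimated correlation), and heat shock genes lower with 0 and 3 down (adjusted p = 0.00778; adjusted p = 0.628 with an estimated correlation). Fatty acid synthesis was lower, with Me1 at -0.34 ± 0.06 past the threshold over all genes (in 13 of 22 alternatives), and 3 down and 1 up adjusted over the list alone (adjusted p = 0.0191; adjusted p = 0.241 with an estimated correlation). The integrated and mitochondrial stress response was higher with Psat1 (0.41 ± 0.08) up over all genes (in 11 of 22 alternatives), and 9 up and 2 down adjusted over the list alone (adjusted p = 0.0368; adjusted p = 0.408 with an estimated correlation). Microglial markers were lower with 0 and 3 down (adjusted p = 0.0277; adjusted p = 0.426 with an estimated correlation), cortex and hippocampus markers lower with no member past either count (adjusted p = 0.0271; adjusted p = 0.628 with an estimated correlation), and orexigenic arcuate markers higher with 0 and 3 up (adjusted p = 0.0391; adjusted p = 0.426 with an estimated correlation). The 40% filter ended the calls of microglia (0.0764) and cortex (0.186), and the mean of probe sets those of FOXO genes (0.0696), arcuate markers (0.0696) and cortex (0.054). Single left-out arrays ended the last 3 calls and those of fatty acid synthesis and the stress response, with adjusted p up to 0.0687, 0.109, 0.139, 0.0549 and 0.103: for microglia knockout fed replicates 2 and 4, for cortex knockout fasted replicate 1 and knockout fed replicate 4, for fatty acid synthesis knockout fasted replicate 3 and knockout fed replicate 2, for the stress response knockout fasted replicates 1 and 3 and knockout fed replicates 1 and 2, and for arcuate markers knockout fed replicates 1, 2 and 3 and fasted replicate 2 of both genotypes.

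The differences between fasted and fed arrays ran in parallel in both genotypes. Of the 472 genes called in control mice and the 119 called in knockout mice, 80 were shared, 60 higher and 20 lower in both, where independent lists would share 1.31 and 0.44. Both contrasts use the same estimate of spread for a gene, so their calls are not independent and chance alone could share more. The sign in knockout mice was that of control mice for 98.1% of the 472. Across all genes the log2 differences of the genotypes, which share no array, had r = 0.699. Genes are not independent replicates, and the highest r among the other splits of the knockout arrays was 0.602. Apart from knockout fed replicate 1, fasted arrays have low sample numbers and fed arrays high ones in both genotypes. A difference between these series would run in parallel too.

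**Figure D4:**
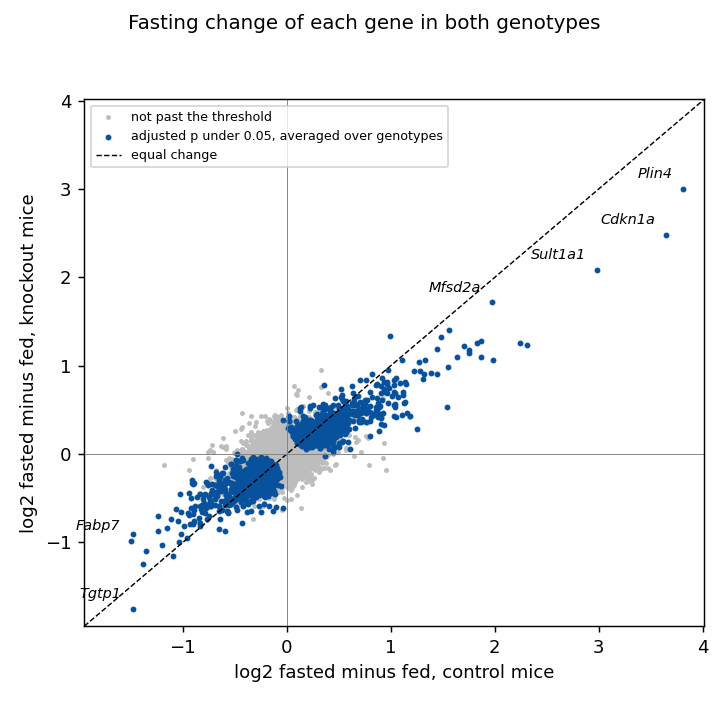
Log2 difference, fasted minus fed, of each gene in control mice (x axis) and in knockout mice (y axis), with the 1715 genes past the threshold in the average in blue. Points along the dashed line changed alike in both genotypes; across all genes r was 0.699.

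The genotype comparison in fed mice (n = 4 each) found 1 gene. Nrip2, which encodes a protein that interacts with nuclear receptors, was lower in knockout mice by 0.45 ± 0.06 on the log2 scale (adjusted p = 0.0396), at 7.58 ± 0.11 (SD) against 8.03 ± 0.05. It is annotated on chromosome 6. It was the only gene of 17097 past the threshold in limma, and 790 had an unadjusted p under 0.05 against 855 by chance. No overlap was seen for 2.46% of all genes, where chance gives 2.86%. Mgst1 (0.49 ± 0.07, adjusted p = 0.0608), Dera (0.45 ± 0.09) and Eps8 (-0.30 ± 0.06), also on chromosome 6, had small p and did not pass, nor did Xlr4c, Ccl25, Spdef, Defb29 and Hrob. The Nrip2 call in fed mice was lost in 10 of the 14 fits that left out 1 array; it was kept without control fasted replicate 2 or 3 and without knockout fed replicate 1 or 2. It was also lost with the mean of its probe sets (-0.28, adjusted p = 0.995), with array medians subtracted, with only the groups compared and with the choroid plexus score as a covariate.

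Choroid plexus markers were higher in fed knockout mice, with a median of 1.42 over 11 genes such as the potassium channel subunits Kcnj13 (2.22 ± 0.97) and Kcne2 (1.95 ± 0.81), Kl (1.74 ± 0.67) and Clic6 (1.09 ± 0.29). The list had an adjusted p of 2.44e-09 (adjusted p = 0.424 with an estimated correlation), with 0 members past the threshold over all genes and 1, Clic6, adjusted over the list alone. The marker score was 0.58 ± 1.29 (SD, n = 4) in knockout fed and -0.74 ± 1.02 (n = 4) in control fed mice. Orexigenic peptides were higher as a list (adjusted p = 0.00143; adjusted p = 0.424 with an estimated correlation), with Npy at 0.46 ± 0.18, Hcrt at 0.40 ± 0.25, Npvf at 0.35 ± 0.15, Pmch at 0.17 ± 0.10 and Gal at 0.17 ± 0.14. Microglial markers were lower (adjusted p = 0.026; adjusted p = 0.424 with an estimated correlation), with Tmem119 at -0.33 ± 0.12 and C1qa at -0.20 ± 0.08. Fatty acid synthesis was higher (adjusted p = 0.026; adjusted p = 0.37 with an estimated correlation) with a median of 0.06, and the mean of probe sets (0.237) or the choroid plexus score as a covariate (0.109) ended this call. None of the members of these 3 lists passed over all genes or adjusted over the list alone. Without control fed replicate 1, which had the lowest orexigenic score of all arrays (-0.60), the adjusted p of orexigenic peptides was 0.0697. This array also had a choroid plexus score of 0.78, but with that score as a covariate the adjusted p of orexigenic peptides was 3.1e-05. The same array had the highest scores of all for cortex and hippocampus (0.80) and meninges (0.58). Its score for POMC neuron markers (-0.34) was the lowest. No fit used those scores as covariates, so the choroid plexus fit does not settle whether tissue content bears on this call. Leaving out control fed replicate 1 also ended the other 2 calls, as did knockout fed replicate 1 for microglia and knockout fed replicate 2 for fatty acid synthesis.

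In fasted mice (n = 3 each), Nrip2 was again the gene with the smallest p, at -0.44 ± 0.07 in knockouts against controls, and did not pass (adjusted p = 0.219). Pla2g4e (-0.83 ± 0.18) and Pdia3 (0.46 ± 0.10), which lie near each other on chromosome 2, Tubd1 (-0.51 ± 0.11) and the cilia genes Rsph9 (0.28 ± 0.06) and Cfap43 (0.33 ± 0.08) had small p without passing. In limma 0 genes passed, and 661 had an unadjusted p under 0.05 against 855 by chance. No overlap was seen for 7.64% of genes, where chance gives 10%. Without knockout fed replicate 1, which enters only the shared estimate of spread, 3 genes passed.

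Glucocorticoid-responsive genes were lower in fasted knockout than in fasted control mice (adjusted p = 6.02e-08; adjusted p = 0.593 with an estimated correlation). The median was -0.37, with Arrdc2 at -0.81 ± 0.36, Ddit4 at -0.60 ± 0.22, Sgk1 at -0.56 ± 0.33 and Tsc22d3 at -0.41 ± 0.20. Without knockout fasted replicate 1, Arrdc2 was at -0.52, Ddit4 at -0.33 and Sgk1 at -0.30. Without knockout fasted replicate 2, Arrdc2 was at -1.30 and Tsc22d3 at -0.67. The list score was 0.51 ± 0.45 (SD, n = 3) in knockout fasted and 0.85 ± 0.19 (n = 3) in control fasted mice, with an exact permutation p of 0.3. With 3 arrays per group this test cannot give a p under 0.1, so it could not have reached 0.05. Knockout fasted replicate 2, at 1.04, lay within the control values of 0.68 to 1.06, and replicates 1 and 3 were at 0.27 and 0.24. The score difference of -0.33 was -0.60 without replicate 2, -0.21 without replicate 1 and -0.20 without replicate 3 of that group. Choroid plexus markers were higher (median 1.31, adjusted p = 2.22e-08; adjusted p = 0.512 with an estimated correlation). Ependyma and tanycyte markers were higher (median 0.22, adjusted p = 0.0109), blood markers higher (median 0.25, adjusted p = 0.041), FOXO genes lower (median -0.07, adjusted p = 0.0289) and astrocyte markers lower (median -0.07, adjusted p = 0.0477), each with adjusted p = 0.512 with an estimated correlation. With the choroid plexus score as a covariate the adjusted p was 0.326 for ependyma and tanycytes and 0.508 for astrocytes, which had 0.143 with the mean of probe sets. None of the members of these 6 lists passed over all genes or adjusted over the list alone. Leaving out 1 array ended each of these last 4 calls, with the adjusted p rising to 0.161 for ependyma and tanycytes (control fasted replicates 1 and 3, knockout fasted replicate 2), 0.39 for FOXO genes (control fasted replicate 2, knockout fasted replicates 1 and 3), 0.192 for blood in 6 of 14 fits and 0.64 for astrocytes in 8 of 14.

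Averaged over feeding states (n = 7 each), Nrip2 was lower in knockouts by 0.45 ± 0.04 (adjusted p = 0.00194), with 7 of 7 knockout arrays at 7.43 to 7.71 and 7 of 7 control arrays at 7.97 to 8.21. It was the only gene past the threshold in limma, and 795 genes had an unadjusted p under 0.05 against 855 by chance. With the mean of its 3 probe sets its adjusted p was 0.162. Smco3 (-0.89 ± 0.14, adjusted p = 0.197), Mgst1, Eps8, Cd9 and Cdkn1b, also on chromosome 6, had small p and did not pass, as did Ovgp1, Sp6, Xlr4b and Zfp764. Without knockout fed replicate 1 the count was 6, and without control fasted replicate 2 it was 2. The choroid plexus markers were the only list past its threshold (median 1.37, adjusted p = 4.57e-15; adjusted p = 0.646 with an estimated correlation). Of 11 members 0 passed over all genes and 10 adjusted over the list alone, with Kcnj13 at 2.14 ± 0.74, Kl at 1.76 ± 0.51 and Clic6 at 1.04 ± 0.22. On the marker scores the genotype difference of 1.35 had an exact permutation p of 0.0143 and of 0.435 after adjustment over the 38 lists. Across genes, the genotype differences of fed and of fasted mice had r = 0.202, and the highest r of the other splits of the fasted arrays was 0.16. By Spearman's method it was 0.029, which 7 of 20 splits reached (highest other 0.083), so no agreement between the feeding states is shown.

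No single gene differed between the genotypes in its fasting response. Npy had an interaction of -0.67 ± 0.28 (adjusted p = 1), Mfn2 of -0.24 ± 0.09 and Sult1a1 of -0.89 ± 0.29. Folh1 (-0.55 ± 0.10), Spdef (0.64 ± 0.12) and Nfatc2ip (0.55 ± 0.11) had the smallest p. In limma 0 genes passed and 654 had an unadjusted p under 0.05 against 855 by chance; 1 passed without knockout fed replicate 1. Simulated interactions of 0.5 on the log2 scale were recovered in 39% of genes, so smaller ones would mostly be missed. That simulation had 200 changed genes and independent noise. With fewer changed genes the adjustment is stricter, so larger interactions could be missed here too. Glucocorticoid-responsive genes had a smaller fasting rise in knockout mice (median interaction -0.41, adjusted p = 2.78e-08; adjusted p = 0.525 with an estimated correlation), with Arrdc2 at -1.08 ± 0.48 and Sgk1 at -0.99 ± 0.44. Knockout fed replicate 4, which stood above the other knockout fed arrays for this list (-0.16 against -0.57 to -0.55), adds to this, and without it Sgk1 was at -0.64. The score interaction of -0.43 was -0.33 without it and -0.69 without knockout fasted replicate 2. The marker lists of microglia (median 0.24) and of ependyma and tanycytes (median 0.26) had a positive interaction, each with an adjusted p of 0.0164 and adjusted p = 0.463 with an estimated correlation. From fed to fasted arrays, the microglial score fell less in knockouts (0.07 to -0.14) than in controls (0.19 to -0.21). The ependyma and tanycyte score fell in controls (0.03 to -0.10) and rose in knockouts (-0.03 to 0.10). None of the members of these 3 lists passed over all genes or adjusted over the list alone. On scores per array, the interaction had an exact permutation p of 0.194 for the glucocorticoid list, 0.0914 for microglia and 0.123 for ependyma and tanycytes, and of 0.969 each after adjustment over the lists. Leaving out 1 array ended the microglia call in 5 of the 14 fits (adjusted p up to 0.168) and the ependyma and tanycyte call in 6 (up to 0.0992), both among them without control fasted replicate 1, control fed replicate 1, knockout fasted replicate 3 or knockout fed replicate 1.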

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

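The tests of interferon-induced genes, choroid plexus scores and chromosome positions in this part were chosen after the result was seen, and so were the 36 interferon-induced genes and the genes named by position. The splits, the correlations and the position of knockout fed replicate 1 over all fasting genes were planned before.

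Of 36 interferon-induced genes, 23 were lower after the fast, 0 higher and 13 did not pass, and many were low in knockout fed replicate 1 as well. The numbers in the sample titles form a low series, with all 6 fasted arrays and this 1 fed array, and a high series with the other 7 fed arrays. On a scale from the other fed arrays (0) to the fasted arrays (1), the array was at 1.03 for these 36 genes, where other fed arrays were at -0.36 to 0.28, at -0.02 for glucocorticoid-responsive genes and at 0.15 for all 1715 fasting genes. The 1715 genes were called with this array counted as fed, which by itself favours a position near 0 for them. A cohort difference in interferon tone is therefore a candidate explanation for the fall of the 23 genes, which could then owe nothing to the fast. The array was below all other fed arrays for 31 of the 36 genes, against 15.7% of all genes and 25.1% of the genes called lower after the fast. A single array cannot separate a cohort from a chance exposure of 1 sample or exclude a series effect on the other fasting genes.

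Choroid plexus markers were higher in knockouts as a list only at the preset correlation (adjusted p = 0.424 in fed, 0.512 in fasted and 0.646 in averaged mice with an estimated correlation). Their scores ranged over 2.21 within the controls, more than the genotype difference of 1.35. Control fed replicate 1, at 0.78, sets that range, and the other controls lay at -1.43 to -0.20. Without it the genotype difference was 1.6. Knockout arrays lay at 0.69 to 1.56, except knockout fed replicate 1 at -1.31. A range and a difference of means are unlike measures, so their comparison decides nothing. Uneven dissection of the ventricle lining is a candidate explanation. With the score as a covariate the adjusted p of the list was 0.607 in fed, 0.628 in fasted and 0.557 in averaged mice, which follows from the construction of the covariate. The exact permutation p of 0.0143, or 0.435 after adjustment, cannot tell dissection from a genotype effect.

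Nrip2 is 1 of 8 genes among the 50 with the smallest p for the averaged genotype that lie within 100 neighbouring genes of chromosome 6, with Itfg2, A2ml1, Cdkn1b, Hebp1, Smco3, Eps8 and Mgst1. Random sets had 4 or fewer in 95% of draws (permutation p = 1e-04, the smallest possible), and the top 50 fasting genes had at most 4 (p = 0.104). A segment of another strain linked to one of the modified alleles is a candidate explanation on this mixed background, and it would make the lower Nrip2 independent of the Mfn1 deletion, which is on chromosome 3. For Nrip2, 2 of 2 other probe sets were lower too (-0.29 ± 0.07 and -0.26 ± 0.08, against -0.45 in the one used). This argues against a sequence variant under that 1 probe set alone. Variants under several probe sets are not excluded, since a segment of another strain could carry them and probe positions were not examined. For Eps8, 1 of 2 was lower (-0.19 ± 0.06, the other -0.09 ± 0.07), and a variant under 1 probe set stays open. The same holds for the 6 genes with no other probe set of a mean over 5. Of these, Cdkn1b has another at a mean of 4.99, which was at 0.04 ± 0.12 against -0.19 ± 0.04 in the one used.

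Splits of the same arrays tell whether chance reaches the counts. For genes, chance is unlikely for fasting in control mice, where 472 was the highest of 35 splits and the next 1. It is unlikely too for the averaged fasting contrast (1715, highest other 1), for which 100 of 1225 splits were counted. In knockout mice 119 was also the highest of 35 splits (next 35). That count was 18 without knockout fasted replicate 2, 21 with the 3' to 5' covariate and 10 with only the groups compared. Splits were not counted under those settings, so the knockout result is less secure. Chance is not excluded for the genotype in fed mice, where 3 of 35 splits reached the count of 1. Another split of the fed arrays gave 43 genes, so a split that mixes the genotypes can give many times the real count. Whether these arrays hold structure other than genotype was not tested. Chance is also not excluded for the averaged genotype (6 of 100 splits, highest other 4). For the interaction and for the genotype in fasted mice the count is 0, which every split reaches (100 of 100 and 10 of 10), so the splits say nothing about chance there. The highest other count was 1 for the interaction and 17 for fasted mice, so splits that mix the genotypes can exceed the real count there too.

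For lists, the count of 10 in the averaged fasting contrast was reached by 2 of 100 splits, the real one included (highest other 10). That share is under the limit of 1 in 20 set before, but another split gave as many lists, so chance is not firmly excluded. Chance is not excluded for fasting in control mice (8 lists, 10 of 35 splits, highest other 14) or knockout mice (9, 2 of 35, highest other 11). Nor is it for the genotype in fed mice (4, 19 of 35, highest other 8), the averaged genotype (1, 91 of 100, highest other 11) or the interaction (3, 50 of 100, highest other 8). Fasted mice have too few splits (6, 1 of 10, highest other 4). The fasting correlation of 0.699 was the highest of 35 splits (next 0.602). That makes chance unlikely but does not exclude a series difference common to both genotypes. The genotype correlation of 0.202 was the highest of 20 splits (next 0.16), which are too few. It was not the highest by Spearman's method (0.029, highest other 0.083) or without control fed replicate 4 (0.175, highest other 0.179).

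In control fed mice single arrays stood apart from the other 3 for some groups. Cholesterol synthesis was at -0.07 in replicate 2 (others 0.07 to 0.09). The growth hormone axis was at 0.12 in replicate 1 (others -0.15 to -0.13), and endothelium and pericytes at -0.14 in replicate 4 (others 0.10 to 0.14). Replicate 1 was also at 0.78 for the choroid plexus (others -1.43 to -1.14) and at 0.80 for cortex and hippocampus (others -0.13 to -0.03).

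In knockout fed mice, replicate 4 was higher for glucocorticoid-responsive genes at -0.16 (others -0.57 to -0.55), Plin4 at 5.55 (4.71 to 4.80), Sgk1 at 10.79 (9.35 to 9.41) and Ccn2 at 6.92 (5.48 to 5.67). Replicate 2 was at 5.48 for Tubd1 (5.26 to 5.29). Replicate 1 was lower for Ifit3 at 6.76 (8.25 to 8.38), Oasl2 at 4.59 (5.75 to 5.81), Gbp2 at 5.14 (5.82 to 5.95), Iigp1 at 4.26 (5.71 to 5.75) and Ifi27l2a at 5.23 (6.41 to 6.54). It was lower as well for Fabp7 at 10.43 (10.59 to 10.60), Dpy19l1 at 8.18 (8.39 to 8.42), glucose sensing at -0.10 (-0.02 to -0.01), stress of the endoplasmic reticulum at -0.07 (0.04 to 0.06) and the thalamus at -0.06 (0.06 to 0.07). Among 160 groups examined this way 20 stood apart, and chance does so for about 1 in 20 groups, or 8.

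The interaction passed for 3 lists at the preset correlation, glucocorticoid-responsive genes (adjusted p = 2.78e-08), microglia (0.0164) and ependyma and tanycytes (0.0164), and for 0 with an estimated correlation (0.525, 0.463 and 0.463). On scores per array the exact permutation p was 0.194, 0.0914 and 0.123, and 0.969 each after adjustment, so a difference between the genotypes is not shown.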

How the results depend on the processing

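Several counts moved when the analysis was varied, and no list call outlasted the estimated correlation. The covariates of choroid plexus score and number series were tests added after the data were seen. Genes that differed between fed and fasted arrays numbered 472 in controls, 770 with a trended and robust prior and 216 to 685 when 1 array was left out. In knockouts the 119 genes became 231 without the 40% lowest genes, 341 with the trended and robust prior, 21 with the 3' to 5' covariate, 10 with only the groups compared and 18 to 363 with 1 array left out. Averaged, the 1715 became 2814 when every probe set was tested and 998 to 2120 with 1 array left out. Counts with every probe set tested are of 45141 probe sets, named or not and several for many genes. They are therefore not on the scale of the gene counts. For the genotype in fed mice the 1 gene became 2 with the 40% filter, the trended prior or array weights, 0 with the mean of probe sets, every probe set, subtracted medians or only the groups compared, and 0 to 3 with 1 array left out. In fasted mice the 0 became 4 with only the groups compared and 0 to 3 with 1 array left out. The averaged genotype count of 1 became 0 with the mean of probe sets, 2 with every probe set, 4 with the trended prior, 4 with the choroid plexus covariate and 1 to 6 with 1 array left out, and the interaction 0 to 1. With the number series as a covariate, which rests on knockout fed replicate 1 alone, the counts were 2 and 0 for fasting in controls and knockouts and 15 averaged, 2, 3 and 6 for the genotype in fed, fasted and averaged mice, and 1 for the interaction. The sign of the called genes was kept for 469 of 472 in controls, 119 of 119 in knockouts and 1682 of 1715 averaged. Among named genes it turned for Ifit3 (0.18) and Oasl2 (0.03) in controls and for Ifit3 (0.054), Iigp1 (0.06), Ifit1 (0.16), Oasl2 (0.04) and Hspb1 (0.034) in the average. Knockout fed replicate 1, which sets this covariate, was at the level of fasted mice for the interferon-induced genes, so their turn follows from that array. For Hspb1 the cause was not tested. With the estimated correlation 0 lists passed in each of the 7 contrasts. The lists with 1 array left out numbered 5 to 10 for fasting in knockouts, 3 to 7 for the genotype in fed and in fasted mice, 1 to 3 averaged and 1 to 6 for the interaction, which had 5 with the 40% filter. The choroid plexus covariate gave 7 lists in fed and 8 in averaged genotypes. The genotype correlation of 0.202 was 0.029 by Spearman's method and 0.133 to 0.273 with 1 array left out. Sex as a covariate was not run, since all arrays had the same male pattern.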

Other observations

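The tests of fasting size were chosen after the result was seen, except the fit without knockout fed replicate 4.

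Some genes of lipid and glucose use rose with the fast, on lists that did not pass. Angptl4, which inhibits lipoprotein lipase, rose by 1.16 ± 0.12 on average (n = 6 fasted, 8 fed; 0.67 with the mean of its probe sets), Pdk4, which spares glucose by blocking pyruvate dehydrogenase, by 1.08 ± 0.20, and Cpt1a, which carries fatty acids into mitochondria, by 0.32 ± 0.05. The fatty acid oxidation list had 5 of 18 members higher and an adjusted p of 0.151. The glucose transporters Slc2a1 (0.63 ± 0.10) and Slc2a4 (0.75 ± 0.19) rose, while the list of glucose, insulin and leptin sensing had 4 of 19 higher and 2 lower (adjusted p = 0.611).

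Dio2, which makes active thyroid hormone, rose by 0.86 ± 0.15 and the thyroid-responsive gene Hr by 0.70 ± 0.15, with an adjusted p of 0.736 and a median of -0.23 for the thyroid list. The clock genes Per1 (0.64 ± 0.12) and Ciart (0.79 ± 0.18) rose and Bhlhe40 fell by 0.31 ± 0.07, with an adjusted p of 0.981 for the list. Immediate early genes Dusp1 (0.73 ± 0.17) and Fos (0.62 ± 0.16) rose, Fos in 14 of 21 alternatives, and so did the cold-inducible gene Cirbp (0.63 ± 0.12). Oligodendrocyte genes went both ways: Cldn11 rose by 0.30 ± 0.05 where Opalin and Ugt8a fell.

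Tmem87a, on chromosome 2, was at 7.93 to 8.15 in knockout fasted, 8.94 to 9.01 in control fasted and 8.93 to 9.08 in control fed arrays. The knockout fed replicates 1 to 4 were at 7.96, 9.04, 8.86 and 8.91. Ppip5k1, on the same chromosome, was at 6.06 to 6.49, 5.07 to 5.19 and 4.87 to 5.13 in those groups, and the knockout fed replicates were at 6.46, 5.45, 5.10 and 4.97. These genes were chosen after their values were seen. Of the 50 genes with the smallest genotype p in fasted mice, 8 lay within 100 neighbouring genes of chromosome 2, Pla2g4e and Pdia3 among them (permutation p = 1e-04, the smallest possible). Knockout fed replicate 1 has the values of the knockout fasted arrays here and shares their low number series, but the control fasted arrays of that series do not have these values.

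The mean fasting change in its own direction was 0.317 in knockout and 0.377 in control mice, a ratio of 0.84. The exact permutation p of 0.416 over 1400 relabellings cannot tell this from equal responses. Knockout fed replicate 4, with higher Plin4 and Sgk1, might have made the response look smaller, and without it the ratio was 0.88. Leaving out other arrays gave 0.67 without knockout fasted replicate 2 and 0.97 without knockout fasted replicate 3, a spread too wide to exclude that array as the cause. A hypothesis to test is that the deletion dampens the rise of glucocorticoid-responsive genes in the fast, for which measured corticosterone in more mice per group could decide.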
